A study of Mus musculus with 1000 samples.

How the data were processed

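The series holds 1000 RNA libraries from mouse brain, each prepared from total RNA and described by the labels with the same tissue, protocols and characteristics. Per the labels' protocols, C57BL/6NCrl founder males received 3 doses of 100 mg/kg of N-ethyl-N-nitrosourea (ENU, a chemical that causes point mutations). By the same protocols, the mutations were bred to homozygosity. Genotypes of single mice are not among the labels, so the mutations that each mouse carried are not known here. Mice of the last generation were usually taken at 8 to 12 weeks of age, and the brain without the cerebellum was used. Per the labels' protocols, 4 ng of RNA per mouse was turned into cDNA from the 3' ends of transcripts with an in-line index and amplified for 8 cycles. The 12 samples of a plate row were then pooled, and 96 such pools made up one sequencing library of 1152 samples. GSNAP, a read aligner, and the mouse genome build GRCm38 are named in the submitters' processing notes. The counting method and the gene annotation are not given in the sources used here.

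The file used here is a list deposited by the authors that pairs each library name with the name of a processed table. It holds 23231 library names and 3 table names, and no expression value, read depth or other measurement. The processed tables themselves were not used here. Expression, sequencing depth and differences between mice were therefore not analysed, no gene is named, and no test was run. The tests of depth and expression planned for the case that the file held such values, with their alternatives, were not run. The reference annotation was not used.

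Each library was joined to the list by its exact title. The title was read as an animal name, a well (row letter and column number), a plate code and a pool number, and this scheme took in the whole list, with 0 names left over. Libraries were grouped into families by the part of the title before the generation mark. The labels do not state that this part names a pedigree, nor that the first part of a title names the animal, so both are readings of the titles. A cDNA pool was taken as a plate code with a row letter. The counts that describe the join and the spread over tables were chosen before the data were examined. The counts of families that fill a pool and of animal names that recur were added after the list was seen. For recurring names, library names outside these 1000 were counted as names only. Counts were called alike when they lay within 1.5 times of each other. The work was done with Python 3.11.15 and pandas 2.3.3.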

Results

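Brain RNA of 1000 mice from an ENU mutagenesis screen was profiled by 3'-end RNA sequencing, with 1 library for each of 1000 different animal names. The screen looked for mice with abnormal inflammation in the brain. The labels give no treated and untreated groups, and the mice were grouped here by family, as read from the titles, which also give the plate and the pool. The data examined here give the place of each library in the experiment and in the processed tables, and not its expression values. Statements on genes, cell types or inflammation were therefore not possible, and the depth of each library is unknown.

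The mice fell into 99 families. Of these, 74 had 12 libraries each and together made up 888 of the 1000 libraries. Another 20 families had 2 to 11 libraries, and 5 families had a single library. These sizes count only the 1000 libraries, and most of the smaller families had more names in the authors' list. Most of these lay on 1 plate, whose code ends in "rep", and each animal name on it recurred elsewhere in the list. Their further names thus include repeats of the same animal names and do not count siblings alone. For example, ENU53002B6 had 6 libraries here and 18 names in the list. Away from that plate, ENU54107B6 had 1 library here and 12 names in the list, and ENU56298B6 had 4 and 12. A few of the smaller families were no larger in the list, such as ENU53140B6 with 6 and ENU53418B6 with 1. A small family here is therefore not always a small pedigree. The labels' protocols state that 12 siblings were typically screened per pedigree, and the median family here also had 12 libraries. The 5 families with 1 library allow no estimate of the spread between siblings within this set.

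The libraries came from 13 plates, and each family lay on a single plate within this set. In the whole list most of these families also lay on 1 plate, but some lay on more, up to 4 for ENU53092B6. In every family on more than 1 plate, the names on other plates included a repeat of an animal name in this set. All 96 wells were represented on 5 plates, and the plate with the fewest of these libraries contributed 16. In the authors' list that plate had 96 names, as had every other plate except the "rep" plate described next. Those plates are thus partly filled here only because this set holds part of their libraries. One plate, whose code ends in "rep", contributed 95 libraries from 20 families. The other 12 plates contributed 905 libraries. A comparison between 2 families on different plates is in this set also a comparison between plates.

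Families were further compared with the cDNA pools, since libraries of a pool were cleaned up and tagged together after cDNA amplification. The 1000 libraries occupied 85 pools, of which 82 were complete with 12 libraries. In 74 complete pools all 12 libraries belonged to 1 family, and that family had no library in another pool of this set. In the other 8 complete pools 2 or more families were mixed, with up to 7 families in a pool. Most of these pools, including the one with 7 families, were on the "rep" plate. The mixed pools on other plates held 2 families each. Of the 99 families, 94 lay in 1 pool and 5, all on the "rep" plate, were divided between 2 pools. For the 74 families that filled a pool, family and pool cannot be told apart within these libraries. Comparisons between mice of one such family are made within a pool. Family and pool also coincided for ENU56298B6, with 4 libraries, and for a family with 1 library. Each was the only family of its pool in this set.

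The titles of all 1000 libraries occurred exactly once in the authors' list of library names. The list assigned its 23231 names to 3 processed tables of 7743 to 7745 names. All 1000 libraries were assigned to 1 of these tables, in which they made up 12.9% of the 7743 names. Within this set, the 94 families with 2 or more libraries and the 13 plates were thus each held in 1 table. With all names of a family in the list taken, this was so for 77 of the 94 families. A comparison among these libraries does not cross processed tables, but the list does not say which of them shared a sequencing library.

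A sequencing library was made of 96 pools, and the titles carry a pool number. Pool numbers 79 and 80 each occurred on 2 plates, so those 2 plates cannot share a sequencing library if the number is unique within it. The smaller of them contributed 16 libraries from 2 families. The other 12 plates, with 984 libraries, had 0 pool numbers in common with one another. Their numbers lay between 1 and 96, so these 12 plates could have formed 1 sequencing library of 96 pools. The labels do not name the sequencing library of any sample. For the 2 families of the smaller plate, a comparison with families of the larger plate would then also be one between sequencing libraries. If the other 12 plates did share 1 sequencing library, the same would hold for a comparison with any of them.

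Repeat libraries were looked for by animal name. All 95 animal names on the "rep" plate recurred elsewhere in the list. Each of them recurred in a processed table other than the one that holds the 1000 libraries, and 1 recurred in that table too. Among the 905 libraries of the other 12 plates, 5 animal names recurred, all in the table that holds the 1000 libraries. That table therefore also holds repeated animal names. Altogether 101 further library names carried the animal name of one of the 1000 libraries. Of these, 95 were on 10 plates without the "rep" ending and 6 were on 1 plate with that ending, which is not the "rep" plate of this set. Libraries that share an animal name do not count as independent mice, and the labels do not say whether such libraries were made from the same RNA.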

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

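No paired analysis was possible because no comparison was tested: the list holds names and no measurements. The match of titles gave 1000 libraries when case, blanks and file endings were ignored and when the read suffix was removed, and the number of tables was 1 when libraries found at least once were taken. Families held in 1 table numbered 94, and 74 when families of 12 alone were taken. These alternatives could not have come out otherwise, since all 1000 titles matched exactly and all lay in 1 table. The 94 and 74 are only the numbers of families counted. When all names of a family in the list were taken, 77 of the 94 families were held in 1 table. Counting plate rows in place of plates raised the number held in 1 table from 13 to 85, by construction, since each plate has several rows. Taking pools from the plate code with the pool number in the title, an alternative chosen after seeing the data, also gave 74 families filling a pool. This was so by construction, since each of the 85 plate rows carried a single pool number, and it says nothing about stability. The count of 95 recurring animal names on the "rep" plate, examined after seeing the data too, was the same when plates with that ending were left out of the search, while the 5 recurring names of the other plates fell to 0. Those 5 names thus recurred on another plate with that ending alone. The depth and expression alternatives were not run. Leaving out single mice was not applicable to these counts.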

Other observations

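The observations here were chosen after the list was seen. The whole list of 23231 library names held 22517 different animal names. Of these, 711 occurred more than once and 3 occurred 3 times, which was the highest number. An analysis of the whole screen that treats each library as a separate mouse would count these animals more than once. All 20 families on the "rep" plate, and no family of the other 12 plates, had further library names in another processed table. Repeat libraries of one animal name in separate tables offer a measure of the spread between libraries, if the tables were normalized alike. Such repeats also differ in plate and table, so that spread would include any difference between these. That spread was not tested, since it needs the expression values.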
